A study of Mus musculus with 6 samples.

How the data were processed

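Total RNA of 6 mouse samples was labelled with biotin and hybridised to Affymetrix arrays, 1 array per sample, starting from 6 µg, per the labels' protocols. The labels name embryos of 13.5 days for all 6 samples, the sample labelled endogenous PV included. Infection with adenovirus was the induction step, and all 6 samples, MEF and the sample labelled endogenous PV included, carry the same text on fibroblast culture and infection, per the labels' protocols. The authors deposited 1 table of log2 values, and Affymetrix Expression Console is named in the submitters' processing notes. The summarisation and normalization algorithm, the software version and the genome build are not given in the sources used here, and the log2 scale was read from the deposited values themselves. The number of arrays, 1 per group, limits the precision.

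The table held 41345 probe sets. Of these, 5333 were numbered below the first annotated probe set and were treated as controls and left out. Exactly 1 gene symbol was given for 23521 probe sets, several for 1814, and 10677 others were unnamed here. Names came from the platform annotation, and 23328 of its Entrez identifiers were found in a RefSeq table of assembly GRCm38.p6, used for names only, which changed 0 symbols. Each of 22180 genes was represented by its probe set with the highest mean over the 6 arrays, and 1082 genes had more than 1. No detection calls were used, so values under the median of all non-control probe sets (5.01) were raised to it. Control probe sets had medians between 4.25 and 4.72 on the arrays. Some genes of the fixed lists are not analysed here.

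The 8 comparisons were day 3 against MEF, day 7 against day 3, day 14 against day 7, day 14 against MEF, sorted cells against unsorted day 14 cells, against MEF and against the array labelled endogenous PV, and the array labelled endogenous PV against MEF. Each gave the difference of log2 values, and genes were counted at a difference of 1 or more (2-fold). No test is possible with 1 array per group, so no p-value or standard error was computed. The technical spread compared the log2 differences, array against array, of the 2 brightest probe sets of 1 gene, both above the floor on both arrays. It was the standard deviation of the difference between these 2 values, divided by the square root of 2, over 328 to 404 genes. The spread leaves out variation between cultures and animals. It includes real differences between transcripts of a gene, which can widen it because it was taken from the same 2 arrays that were compared. Simulated unchanged arrays drew errors from this spread 1000 times. Tested on simulated data with 200 changed genes among 22180, the count recovered 50.5% of genes changed 2-fold and 100% of those changed 4-fold for day 3 against MEF. For sorted cells against MEF it recovered 56.5% and 96.0%, and for day 14 against MEF 46.5% and 97.5%. The changed genes were drawn from those more than 1 log2 unit above the floor, so this does not cover genes near the floor. A change equal to the threshold passes or fails by the drawn error alone.

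For each of 32 gene lists, the median difference of members above the floor on at least 1 array was placed among 10000 random lists of the same size matched on expression in 20 bins. Of 251 medians, 61 lay above percentile 97.5 and 32 below percentile 2.5, where random lists would give 12.6 in all. Random lists draw genes independently. The fixed lists hold genes that may vary together, some share members, and the comparisons share arrays. The excess is therefore a description and not a test. The comparisons, gene lists, floor, size threshold, named-gene rule and first 6 alternatives were chosen before the data were examined. The named genes were, in each comparison, the 10 with the largest floored difference in each direction, and up to 4 members of every list with the largest floored difference. For the first part, every probe set with 1 symbol above the floor on either array had to differ in the same direction, and predicted genes without a proper name were left out. A further part was a preset list, of which the genes analysed were Pvalb, Gad1, Gad2, Slc32a1, Tubb3, Map2, Dcx, Rbfox3, Col1a1, Col1a2, Vim, Mki67, Sst, Slc17a7, Slc17a6, Th, Gfap, Mbp, Rest and Myod1. The text gives a selection of the genes this rule named, made after their values were seen. Which list medians to print was decided after the data were seen, as 4 lists of the question and every list beyond those percentiles in each comparison, and every list with a measured member for sorted cells against MEF. All 12 neuronal lists were given in the other comparisons of sorted cells or the array labelled endogenous PV. For the array labelled endogenous PV against MEF, lists of opposite sign in sorted cells were added, 7 in all. Similarity was Pearson correlation over floored values.

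Alternatives were quantile normalization, centring each array on the median of housekeeping genes, the mean of all probe sets of a gene, no floor, a floor at percentile 75, and a 4-fold threshold. The centring subtracts the difference between the medians of 2 arrays over housekeeping genes, which is not the median difference of single housekeeping genes. With no floor every analysed member of a list counted. With the floor at percentile 75 only members above 6.58 on at least 1 array counted, so the members of a list changed with the floor. Taking probe sets and floor from the 5 arrays other than the one labelled endogenous PV was added after seeing the data. A list median was called moved when it shifted by more than the technical spread times the square root of pi over 2, divided by the square root of the number of members. A gene was called moved beyond 1 technical spread, a count beyond 1.5 times, and a share outside its 95% Wilson interval. Differences of correlations were judged by the same 1.5 times. These tolerances were also set after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.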

Results

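Total RNA of 6 mouse cell samples was measured on single-colour expression arrays, with 1 array in each group. The groups were mouse embryonic fibroblasts (MEF), fibroblasts induced toward parvalbumin neurons (iPV) after 3, 7 and 14 days, iPV cells at 14 days sorted for green fluorescence, and a sample labelled endogenous parvalbumin (PV) neurons. Parvalbumin neurons are fast-spiking inhibitory neurons, and in the PV-GFP mice used here, of strain C57BL/6, a transgene marks them with green fluorescent protein. The question behind the series was how far the expression profile of induced fibroblasts approaches that of parvalbumin neurons. Values were log2 intensities of 22180 genes. Because no group had a replicate, no difference below has a replicate check, and each describes the arrays compared. Values under a floor of 5.01, the median of all non-control probe sets, were raised to it, so a fold against such a value is a lower bound, written "at least". Directions of lists were checked under quantile normalization and under centring on housekeeping genes. That centring moved the median of all genes to -0.26 for day 3 against MEF, -0.19 for day 7 against day 3, -0.46 for day 14 against MEF, 0.17 for sorted against unsorted cells, -0.31 for sorted cells against MEF and -0.28 for the array labelled endogenous PV against MEF, so those lists are to be read relative to these shifts. Shifts of a list median that stayed within its technical error are given only in part.

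Parvalbumin and the GABA synthesis and transport genes Gad1, Gad2 and Slc32a1 had low values on all 6 arrays. Pvalb, which encodes parvalbumin, had 5.23 in MEF, 5.76 at day 3, 6.15 at day 7, 5.80 at day 14, 6.29 in sorted cells and 5.48 on the array labelled endogenous PV. Gad1, a synthetic enzyme of the transmitter GABA, lay between 4.68 in sorted cells and 5.19 in MEF. Gad2, the other such enzyme, lay between 4.09 on the array labelled endogenous PV and 4.93 at day 3, under the floor on every array. Slc32a1, the vesicular GABA transporter, lay between 4.46 in sorted cells and 5.21 at day 14. Fibroblast genes were bright on every array, including the array labelled endogenous PV. There Col1a1, a chain of type I collagen, had 12.34 and Vim, an intermediate filament protein, had 11.58, against 12.31 and 12.58 in MEF. Among other neuronal markers, Dcx stayed under the floor on all 6 arrays, at most 4.59 in sorted cells, and Rbfox3 lay between 5.29 on the array labelled endogenous PV and 6.06 at day 14. Tubb3, a neuronal tubulin, lay between 5.69 and 6.17 on the other 5 arrays and had 7.16 in sorted cells, and Slc17a7, a vesicular glutamate transporter, lay between 4.43 and 4.88 and had 6.06 there. Map2, a microtubule protein of dendrites, had 7.20 in MEF, 6.07 at day 14, 7.19 in sorted cells and 6.58 on the array labelled endogenous PV. Sst lay between 5.33 and 5.66, Slc17a6 between 3.51 and 3.99, Th between 4.58 and 5.10, Gfap between 4.46 and 4.98, and Mbp between 5.02 and 5.45. Rest, a repressor of neuronal genes, lay between 6.90 and 7.13, and Myod1, a muscle regulator, between 5.08 and 5.76.

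**Figure D1:**
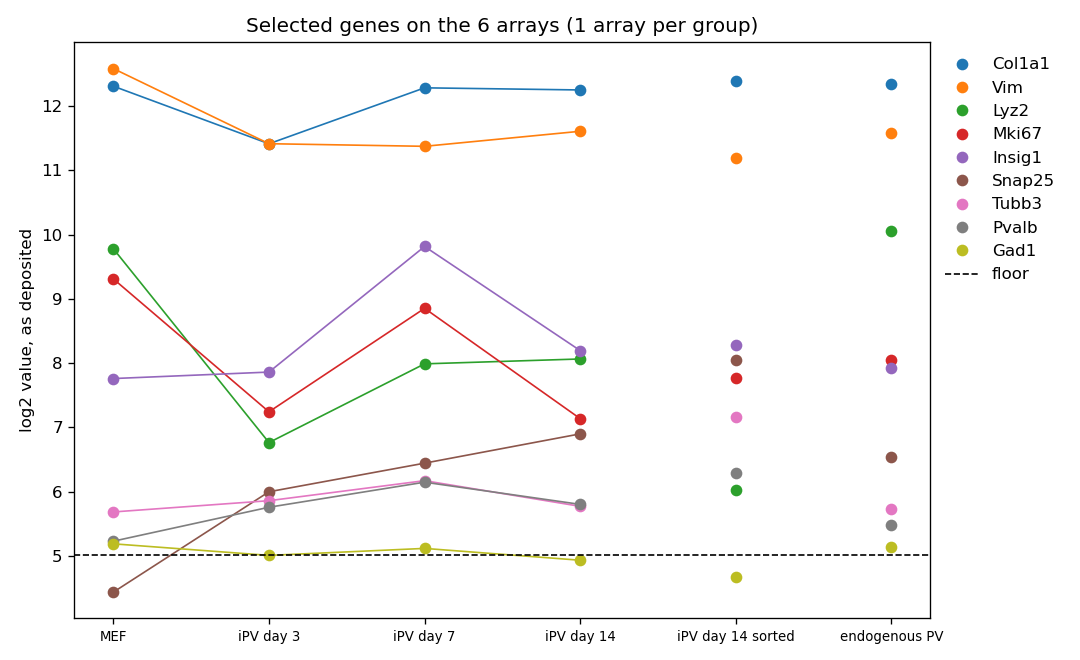
Points give the deposited log2 value of 9 genes on each of the 6 arrays, with lines joining MEF and the induced days and a dashed line at the floor of 5.01. Col1a1 was at 11.41 or above on every array, while Gad1 stayed near the floor and Snap25 was highest in sorted cells at 8.05.

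At day 3 of induction, genes of cell division and extracellular matrix were lower than in MEF, and interferon-response genes were higher. Of 34 measured cell cycle genes, 16 were at least 2-fold lower and 0 higher, with a median log2 difference of -0.96 that lay below all random lists matched on expression. Mki67, a proliferation marker, differed by -2.07 and Cenpe, a kinetochore motor, by -1.89. In the fibroblast and matrix list, 10 of 36 genes were lower and 2 higher, with a median of -0.65. Col6a3, a chain of type VI collagen, differed by -2.52 and S100a4 by -2.33, while Fap, a surface protease of activated fibroblasts, was higher by 2.04. Macrophage genes had a median of -1.28 over 15 measured members, with 9 lower and 1 higher. Lyz2, which encodes lysozyme, differed by -3.01 and Fcer1g by -2.52. Interferon-response genes had a median of 0.74, with 7 of 25 higher and 0 lower, among them Bst2 by 2.36 and Usp18 by 1.73. In the cerebellum and hindbrain list, 5 members were measured, with a median of 0.51 at percentile 99.5, and 0 of them passed 2-fold. That median was 0.093 after housekeeping centring and 0.14 both with no floor and with a floor at percentile 75. En1 was higher by 0.57 and Zic1 by 0.51. Hox genes had a median of 0.50 with 3 of 23 higher and 0 lower.

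Other lists above the upper percentile limit at day 3 were proneural regulators at 0.37 with 3 of 19 higher and 1 lower, other interneuron classes at 0.34 with 2 of 10 higher and 1 lower, and GABA and glutamate receptors at 0.29 with 1 of 9 higher. The p53 response, at 0.28 with 0 of 16 differing 2-fold, and the respiratory chain, at 0.25 with 1 of 28 lower, were also above it. Below the lower limit were astrocytes at -0.50 with 1 of 9 higher and 1 lower, cholesterol synthesis at -0.34 with 0 of 18 differing 2-fold and glutamatergic neurons at -0.29 with 1 of 7 lower. Housekeeping centring gave 0.21 for Hox genes, 0.084 for proneural regulators, 0.092 for other interneuron classes, 0.0044 for receptors and 0.0016 for the p53 response. It turned the respiratory chain to -0.037 and gave -0.62 for cholesterol synthesis and -0.57 for glutamatergic neurons. Without a floor astrocytes turned to 0.097 and glutamatergic neurons to 0.031, and proneural regulators were at 0.23. The floor at percentile 75 gave 1.5 for other interneuron classes, 0.58 for proneural regulators, 0.16 for the respiratory chain, -0.017 for astrocytes and -0.58 for glutamatergic neurons.

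The gene furthest below MEF among those named at day 3 was Txnip, an inhibitor of glucose uptake, with a log2 difference of -6.57. Mmp13, a collagenase, was 26.1-fold lower and Prelp, a matrix proteoglycan, 23.5-fold lower. Folh1 was at least 23.7-fold higher, Ankrd1 20.5-fold, Bex1 at least 16.8-fold and Npy1r, a receptor of neuropeptide Y, at least 8.93-fold. Calb2, which encodes the interneuron protein calretinin, was at least 8.42-fold higher, and Cck, a neuropeptide gene, was higher by 2.95 on the log2 scale. Of the lists of the study's question, GABAergic neurons had a median of 0.13 with 1 of 5 measured members at least 2-fold higher, parvalbumin interneurons 0.20 with 0 of 14 and pan-neuronal genes 0.15 with 0 of 22, and each of these medians was negative after housekeeping centring. With a floor at percentile 75 the medians were 0.32 for GABAergic neurons, -0.14 for parvalbumin interneurons, -0.11 for pan-neuronal genes, -0.50 for cell cycle and 0.49 for interferon response. In all, 318 genes were at least 2-fold higher and 363 lower at day 3. The technical spread between probe sets of 1 gene was 0.32, and arrays simulated with no change gave 80 such genes. Centring on housekeeping genes moved the share of higher genes from 46.7% to 20.5%, and a 4-fold threshold turned the majority, with 62 higher and 48 lower.

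Between days 3 and 7, cell cycle and cholesterol synthesis genes were higher on the later array. Of 34 cell cycle genes, 23 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.15 above all random lists. Ccna2, a cyclin of S phase, was higher by 2.15, Kif11, a spindle motor, by 1.68 and Mki67 by 1.61. Of 18 cholesterol synthesis genes, 9 were higher and 0 lower, with a median of 1.01. Insig1, a sterol-regulated control protein, was higher by 1.95, Cyp51, a demethylase of sterol synthesis, by 1.67 and Sqle, the squalene epoxidase, by 1.51. Fibroblast and matrix genes had a median of 0.36 with 2 of 36 higher and 1 lower, Tgfbi higher by 1.75 and Col3a1 by 1.74, against Twist2, a mesenchymal transcription factor, at -1.65. Macrophage genes had a median of 0.62 with 3 of 13 higher and 0 lower, among them Cd14 by 1.30 and Lyz2 by 1.22. Astrocyte-list genes had a median of 0.43 with 1 of 9 higher, Aldoc higher by 1.14. Other lists beyond the percentile limits were glycolysis at 0.37 with 0 of 14 differing 2-fold, cerebellum and hindbrain at 0.27 with 0 of 7, synaptic vesicle and active zone at 0.26 with 2 of 17 higher, and interferon response at -0.27 with 0 of 25. Housekeeping centring gave 0.20 for glycolysis, 0.086 for synaptic genes and -0.44 for the interferon response.

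Txnip was 39.3-fold higher at day 7 than at day 3, and Reg3g, an antimicrobial lectin, was 13.7-fold higher. Prelp was 8.85-fold higher and Mup3, a major urinary protein, at least 11.5-fold. Ankrd1 was 4.48-fold lower and Ddit3, a stress-response transcription factor, 4.21-fold lower. GABAergic neuron genes had a median of -0.03 and parvalbumin interneuron genes -0.014, of which the latter turned positive after quantile normalization. Pan-neuronal genes had a median of 0.15, negative after housekeeping centring, and 0 members of these 3 lists differed 2-fold. A floor at percentile 75 turned the GABAergic median positive and gave -0.32 for parvalbumin interneurons, 0.44 for pan-neuronal genes, 1.22 for macrophages and 0.090 for astrocytes. Housekeeping centring gave -0.19 for parvalbumin interneurons, 0.18 for fibroblast and matrix genes and 0.25 for astrocytes, which were at 0.23 with no floor. In total 288 genes were at least 2-fold higher and 117 lower, with a technical spread of 0.33 and 117 genes from simulated unchanged arrays. The share of higher genes was 71.1%, with 42.0% after housekeeping centring, 56.2% with no floor and 92.0% at 4-fold.

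At day 14, cell cycle and cholesterol synthesis genes were lower than at day 7, while interferon-response and p53-response genes were higher. Cell cycle genes had a median of -1.05, with 18 of 34 at least 2-fold lower and 0 higher, including Top2a, a DNA topoisomerase, at -1.81 and Ccnb2 at -1.65. Cholesterol synthesis genes had a median of -0.96 with 9 of 18 lower and 0 higher, Insig1 at -1.62 and Hmgcs1 at -1.48. Interferon-response genes had a median of 0.92, and 12 of 25 were higher and 0 lower, with Rsad2 at 1.67 and Cxcl10, a chemokine, at 1.55. Of 16 p53-response genes, 3 were higher and 0 lower with a list median of 0.58, namely Perp at 1.44, Mdm2, the p53 ligase, at 1.28 and Btg2 at 1.16. Among fibroblast and matrix genes the median was -0.13 with 1 of 36 lower and 0 higher, Tgfbi at -2.97. The cAMP and activity response had a median of 0.33 with 5 of 19 higher and 0 lower, and 0.95 with a floor at percentile 75. Endothelial genes were at 0.38 with 0 of 6 differing 2-fold, which turned to -0.063 with no floor. Astrocyte genes were at -0.27 with 0 of 9 differing 2-fold, and -0.090 with the higher floor, and Hox genes at -0.12 with 0 of 24.

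Egr1, an immediate early gene, was 6.23-fold higher at day 14 than at day 7, and the prolactin family gene Prl3a1 was 5.79-fold higher. Pi15 was 7.47-fold lower, Agtr2, an angiotensin receptor, 6.50-fold lower and Ptn, a growth factor, 5.77-fold lower. Median differences of the remaining lists of the question were 0.06 for GABAergic neurons with 0 of 6 differing 2-fold, -0.03 for parvalbumin interneurons with 1 of 14 higher, and -0.08 for pan-neuronal genes, where 1 of 22 was lower, Tubb4a at -1.06. The parvalbumin interneuron median turned to 0.83 with a floor at percentile 75, and the pan-neuronal median was -0.48 with that floor and -0.0056 after quantile normalization. The GABAergic median turned negative with no floor and with the mean of probe sets. Counts were 134 genes higher and 183 lower, a share of 42.3% higher and 28.6% at 4-fold, with a technical spread of 0.28 and 0 genes from simulated unchanged arrays. The simulation drew only from the errors of 359 genes, and a 0 follows when none of these reaches 2-fold. It does not show that unchanged arrays give no such genes.

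Compared with MEF, the day 14 array had higher interferon, glycolysis and p53-response genes and lower cell cycle genes. Interferon-response genes had a median log2 difference of 1.54, with 17 of 25 at least 2-fold higher and 0 lower. Irf7, a regulator of interferon genes, was higher by 2.73, Usp18 by 2.61 and the chemokine gene Cxcl10 by 2.49. Cell cycle genes had a median of -0.88 with 14 of 34 lower and 0 higher, Mki67 by -2.17 and Prc1 by -1.91. Glycolysis genes had a median of 0.73 with 3 of 14 higher and 0 lower, with Hk2, a hexokinase, higher by 1.84 and Pfkl, a phosphofructokinase, by 1.53. The p53-response list had a median of 0.68, with 4 of 16 higher and 0 lower, including Sesn2 at 1.66. For macrophage genes the median was -0.62, with 5 of 16 lower and 1 higher. Fibroblast and matrix genes had a median of -0.18, with 6 of 36 lower and 1 higher, Tgfbi at -3.19 and Fap at 1.95. Fmo2 was 31.5-fold higher, Calb2 at least 21.7-fold, Prl8a9 18.5-fold and Sema3e, a guidance factor, 15.0-fold, while Lgr5 was 21.1-fold and Grem1 9.27-fold lower.

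Another 5 lists lay above the upper percentile limit at day 14 against MEF and turned negative after housekeeping centring. Their medians were 0.44 for the respiratory chain with 1 of 28 higher, 0.41 for synaptic vesicle and active zone with 2 of 18, 0.39 for GABA and glutamate receptors with 1 of 9, 0.39 for smooth muscle and myofibroblasts with 1 of 17 and 0.32 for Hox genes with 3 of 23, and 0 members were lower. After that centring they were -0.055, -0.062, -0.0078, -0.11 and -0.17 in the same order. Housekeeping genes themselves differed by a median of 0.25 in this pair, less than any of the 5 medians before centring. The centring subtracted more than this, because it used the median over housekeeping genes on each array, 8.94 at day 14 and 8.45 in MEF. Receptors were at 0.14 with no floor and with a floor at percentile 75, and smooth muscle at 0.14 with the mean of probe sets. The cAMP and activity response had a median of 0.45 with 4 of 18 higher and 0 lower, which was 0.060 after housekeeping centring and 0.80 with the higher floor.

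Parvalbumin interneuron genes at day 14 had a median of 0.31 with 1 of 13 at least 2-fold higher and 0 lower. This lay at percentile 98.6 of random lists and turned to -0.18 after housekeeping centring. Housekeeping genes themselves differed by a median of 0.25, less than the parvalbumin interneuron median. The centring subtracted more than this, because it used the array medians given above. Of the parvalbumin interneuron genes, Hapln4, a link protein of perineuronal nets, was higher by at least 1.04 and Cox6a2 by 0.67. GABAergic neuron genes had a median of 0.28 with 1 of 6 higher, Abat, the GABA transaminase, by 1.31. Pan-neuronal genes had a median of 0.20 with 1 of 23 lower, Map2 at -1.13, and both medians were negative after housekeeping centring. That centring also gave -0.68 for fibroblast and matrix genes, -1.37 for cell cycle, 0.24 for glycolysis, 0.19 for the p53 response and -1.07 for macrophages. The higher floor at percentile 75 gave -0.23 for pan-neuronal genes and -0.44 for cell cycle. A total of 466 genes were at least 2-fold higher and 279 lower. The technical spread was 0.43 and simulated unchanged arrays gave 327 genes. The share of higher genes was 62.6%, against 14.0% after housekeeping centring.

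Sorted cells at day 14 had higher pan-neuronal genes and markers of other interneuron classes than unsorted cells of the same day, while several other neuronal lists lay within the percentile limits. Of 24 measured pan-neuronal genes, 6 were at least 2-fold higher and 0 lower, with a median log2 difference of 0.65 above all random lists. Tubb4a, another tubulin, was higher by 1.52, Ina, a neuronal intermediate filament, by 1.44, Tubb3 by 1.39 and Chga, a protein of secretory granules, by 1.32. Markers of other interneuron classes had a median of 0.55 with 3 of 12 higher and 0 lower, with Prox1 higher by 1.77 and Htr3a, a serotonin receptor, by 1.41. The list of REST-related repressors and neuronal splicing factors had a median of 0.47 with 1 of 14 higher and 0 lower, Rbfox1 by at least 1.10. Hox genes, which mark body position, had a median of 0.45 with 2 of 25 higher and 0 lower, Hoxa5 by 1.32 and Hoxa2 by 1.02. Smooth muscle and myofibroblast genes had a median of -0.49, with 4 of 17 lower and 0 higher, among them Ccn2, a matrix-associated growth regulator, at -2.15 and Tagln at -1.32. For macrophage genes the median was -0.34, with 3 of 15 lower and 0 higher, and interferon-response genes a median of -0.42 with 0 of 25 differing 2-fold. Voltage-gated channels were at 0.38 with 1 of 9 higher, and 0.16 with no floor. Proneural regulators were at 0.26 with 3 of 21 higher and 0 lower, which turned to -0.036 with no floor and was 0.15 after quantile normalization and 0.40 after housekeeping centring. Glycolysis genes were at -0.29 with 0 of 14 differing 2-fold, -0.10 after housekeeping centring and -0.16 with the mean of probe sets. Pluripotency genes were at -0.37 with 0 of 4 differing 2-fold.

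Neuronal lists within the percentile limits in this pair included medial ganglionic eminence regulators at 0.20 with 0 of 8 differing 2-fold, synaptic vesicle and active zone at 0.16 with 2 of 19 higher, and glutamatergic neurons at -0.053 with 2 of 8 higher and 1 lower. GABA and glutamate receptors were at -0.061 with 1 of 8 higher, and other transmitter systems at -0.16 with 0 of 3 differing 2-fold. Housekeeping centring turned glutamatergic neurons to 0.16, receptors to 0.11 and other transmitter systems to a positive value, and gave 0.34 for synaptic genes, which were at 0.061 after quantile normalization. The floor at percentile 75 gave 0.66 for synaptic genes, 0.22 for glutamatergic neurons and 0.042 for medial ganglionic eminence regulators, and without a floor glutamatergic neurons were at -0.28.

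In sorted against unsorted cells Scube1 was 7.29-fold higher and Kcnn3, a calcium-activated potassium channel, 5.93-fold. Mmp3 was 9.86-fold lower. Ccl3, a chemokine gene, was 7.67-fold lower and Lilrb4a, a leukocyte receptor gene, 5.68-fold. Lyz2 differed by -2.04. Fibroblast and matrix genes had a median of -0.03, positive after housekeeping centring, with 1 of 36 higher and 0 lower. Parvalbumin interneuron genes had a median of -0.06, also positive after that centring, with 1 of 14 lower, Kcnab1 at -1.64, and 1 higher, Ppargc1a by at least 1.08. GABAergic neuron genes had a median of 0.10, negative after quantile normalization, with 0 of 5 differing 2-fold, and Abat was higher by 0.83. The GABAergic list median turned to -0.16 with no floor and was 0.55 with a floor at percentile 75, which also turned the parvalbumin interneuron median to 0.026 and gave 0.39 for pan-neuronal genes and 0.13 for the REST-related list. The same 0.026 came out against MEF and against the array labelled endogenous PV. A member under that floor on every reference array would give this, so it does not describe the pair. Housekeeping centring gave -0.31 for smooth muscle genes, -0.15 for macrophages and -0.23 for the interferon response. In this pair 280 genes were at least 2-fold higher and 135 lower, with a technical spread of 0.33 and 67 genes from simulated unchanged arrays. The share of higher genes was 67.5%, with 86.4% after housekeeping centring and 56.6% with no floor. At 4-fold the majority turned, with 9 genes higher and 13 lower, a share of 40.9%.

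Against MEF, sorted cells had higher pan-neuronal, synaptic, Hox and interferon-response genes and lower cell cycle genes. Pan-neuronal genes had a median log2 difference of 0.71, with 10 of 25 at least 2-fold higher and 0 lower, including Chga by at least 1.96 and Ina by at least 1.88. Synaptic vesicle and active zone genes had a median of 0.59 with 5 of 18 higher and 0 lower. Snap25, a protein of synaptic vesicle fusion, was higher by at least 3.04, and Rab3a, a vesicle GTPase, by 1.37. Hox genes had a median of 0.89 with 8 of 24 higher and 0 lower, Hoxa5 by 2.25. Synaptic and Hox genes also lay above the upper percentile limit against MEF in unsorted day 14 cells and on the array labelled endogenous PV, and Hox genes at day 3. Interferon-response genes had a median of 1.09 with 13 of 25 higher and 0 lower, Ccl5 by 2.26. Cell cycle genes had a median of -0.90 with 16 of 34 lower and 0 higher, Cenpe by -1.92, and fibroblast and matrix genes a median of -0.33 with 8 of 36 lower and 1 higher, Thbs1 by -1.65. Macrophage genes had a median of -0.84 with 7 of 15 lower and 1 higher, and Lyz2 was 13.5-fold lower. Calb2 was at least 29.2-fold higher, Sparcl1 21.0-fold and Lrat, an enzyme of retinoid storage, at least 20.6-fold. Housekeeping centring gave 0.29 for pan-neuronal, 0.24 for synaptic, 0.58 for Hox and -0.64 for fibroblast and matrix genes. The floor at percentile 75 gave 0.31 for pan-neuronal, 0.92 for synaptic, -0.47 for cell cycle and -0.49 for macrophage genes, and the mean of probe sets gave 0.45 for pan-neuronal genes.

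GABAergic neuron genes in sorted cells against MEF had a median of -0.05 with 1 of 5 higher, Abat by 2.15. The median turned to 0.98 with a floor at percentile 75, where fewer members counted and Gad1 was not among them. Parvalbumin interneuron genes had a median of 0.20 over 14 members, with 3 higher and 1 lower, which turned negative after housekeeping centring and was 0.026 with that floor. Pvalb itself was higher by 1.06, where the technical spread was 0.50. Its values, 5.23 in MEF and 6.29 in sorted cells, both lay under the floor at percentile 75. Glutamatergic neuron genes had a median of -0.0038 with 2 of 8 higher, Camk2a by 1.66 and Slc17a7 by at least 1.04. The list of other transmitter systems had a median of -0.07 with 0 of 4 differing 2-fold. Voltage-gated channels had a median of 0.37 with 2 of 10 higher, among them Scn3b, a sodium channel subunit, by 1.87, and GABA and glutamate receptors a median of 0.13 with 2 of 10 higher, among them Gabbr1, a metabotropic GABA receptor, by 1.31. Regulators of the medial ganglionic eminence, where these interneurons arise, had a median of 0.0017 with 0 of 8 differing 2-fold, negative after housekeeping centring, with no floor and with a floor at percentile 75. The higher floor turned the glutamatergic median to 0.23 and gave 1.07 for voltage-gated channels and 0.88 for receptors, which were at 0.46 with no floor, where the glutamatergic median was also positive. Housekeeping centring gave 0.064 for voltage-gated channels and -0.31 for glutamatergic neurons.

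Other lists in sorted cells against MEF covered other cell types and pathways. Other interneuron classes had a median of 0.82 with 6 of 12 higher and 0 lower, and 0.27 with no floor. Proneural regulators were at 0.46 with 6 of 21 higher and 1 lower, which was 0.16 after housekeeping centring, 0.15 with no floor and 0.81 with a floor at percentile 75. The p53 response was at 0.52 with 2 of 16 higher, the REST-related list at 0.50 with 4 of 14 and glycolysis at 0.46 with 3 of 14, against 0.21, 0.19 and 0.15 after housekeeping centring, and the REST-related list was at 0.12 with the higher floor. Smooth muscle and myofibroblast genes were at -0.24 with 1 of 17 higher and 2 lower, and -0.54 after housekeeping centring. Astrocytes were at 0.18 with 1 of 9 higher, cerebellum and hindbrain at 0.15 with 0 of 7 and cholesterol synthesis at 0.031 with 0 of 18, and all 3 were negative after that centring, at -0.13 and -0.28 for astrocytes and cholesterol synthesis. Cholesterol synthesis also turned negative after quantile normalization. The cerebellum and hindbrain list was at -0.10 with no floor and 0.50 with the higher floor.

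Respiratory chain genes had a median of 0.31 with 2 of 28 higher. Medians were 0.22 for cAMP and activity response with 4 of 19 higher, 0.029 for skeletal muscle with 2 of 17 and 0.027 for the oligodendrocyte lineage with 1 of 8, and these 3 medians were negative after housekeeping centring. Skeletal muscle was at -0.14 with no floor, 0.23 after quantile normalization and 1.45 with a floor at percentile 75, which gave 0.93 for the oligodendrocyte lineage. Endothelial genes had a median of -0.28 with 1 of 6 lower, Schwann cell and neural crest genes -0.13 with 2 of 10 higher, and pluripotency genes -0.14 with 0 of 4 differing 2-fold. With that floor the medians were -0.65 for endothelium and 0.32 for Schwann cell and neural crest genes, which were at -0.42 after housekeeping centring, where the respiratory chain was at 0.0006. Des, an intermediate filament of muscle, was higher by 3.17, Cldn11 by 1.91 and Sik1, a cAMP-responsive kinase, by 2.02, whereas Flt1, a receptor of vascular growth factor, differed by -2.48. Of the erythroid list 1 member was measured, Epb42, higher by 0.28. Housekeeping genes had a median of 0.14 with 2 of 20 lower, negative after centring on the list itself. In this comparison 814 genes were at least 2-fold higher and 364 lower. The technical spread was 0.50, the largest of the 8 comparisons, and simulated unchanged arrays gave 699 genes. Real differences between transcripts of a gene can raise both, so 699 is not a count expected without any change. The share of higher genes was 69.1%, against 36.0% after housekeeping centring and 58.3% after quantile normalization.

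**Figure D2:**
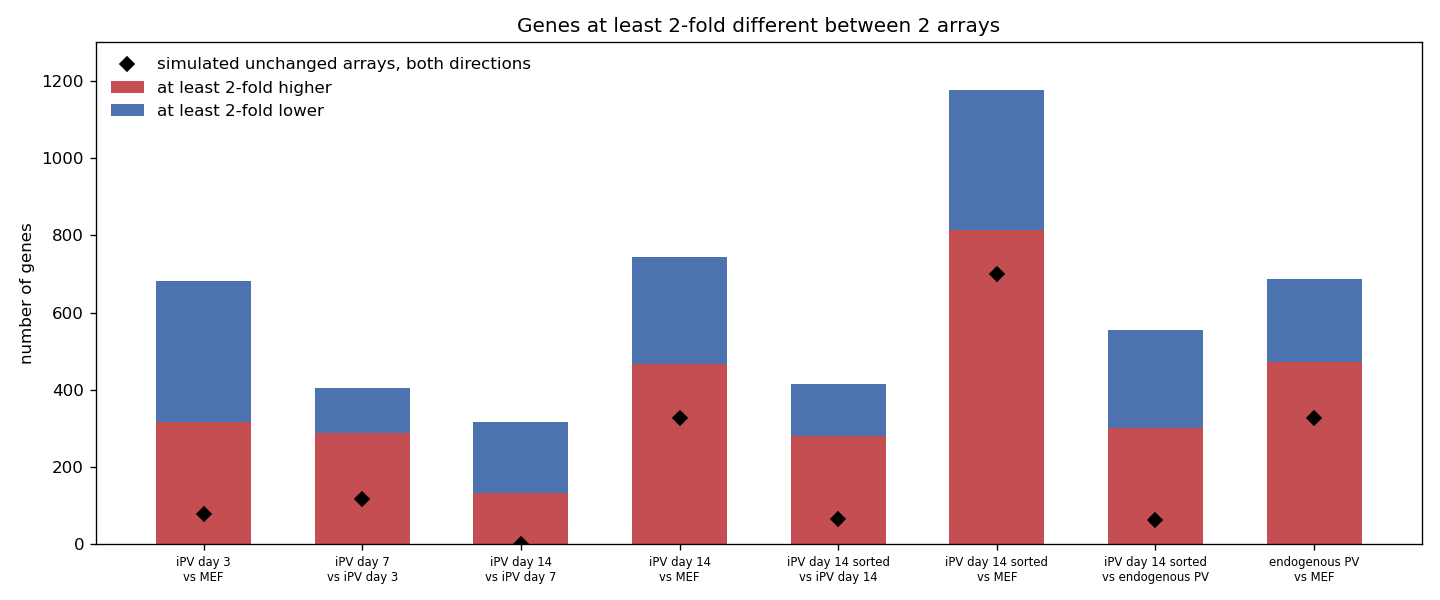
Stacked bars give the number of genes at least 2-fold higher and lower in each of the 8 comparisons, and diamonds the number from simulated unchanged arrays in both directions. Sorted cells against MEF had 814 higher and 364 lower genes, with 699 from simulated unchanged arrays. Real differences between transcripts of a gene can raise the simulated numbers.

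Sorted iPV cells had higher pan-neuronal, other interneuron and proneural genes, and lower macrophage and interferon genes, than the array labelled endogenous PV. Pan-neuronal genes had a median log2 difference of 0.64, with 10 of 24 at least 2-fold higher and 1 lower. Ina was higher by 1.79, Tubb3 by 1.43 and Nefl, a neurofilament, by at least 1.40. Other interneuron classes had a median of 0.81 with 5 of 12 higher and 0 lower, Htr3a by 1.80 and Calb2 by 1.21. Proneural and neurogenic regulators had a median of 0.37 with 2 of 21 higher, Dll3, a Notch ligand, by 1.69 and Hes6 by 1.42, and 1 lower, Ebf1 at -1.46. Macrophage genes had a median of -1.22 with 9 of 16 lower and 0 higher, Fcer1g at -2.74 and Adgre1 at -2.68 or beyond. Interferon-response genes had a median of -0.49 with 4 of 25 lower and 0 higher, Irf7 at -1.20. Fibroblast and matrix genes had a median of -0.38, with 2 of 36 lower and 0 higher, Lum, a matrix proteoglycan, at -1.22 and Col3a1 at -1.16. Smaller medians beyond the percentile limits were 0.32 for voltage-gated channels with 0 of 10 differing 2-fold, 0.28 for skeletal muscle with 2 of 14 higher, 0.25 for the respiratory chain with 0 of 28 and 0.25 for cholesterol synthesis with 0 of 18. Smooth muscle and myofibroblast genes were at 0.23 with 1 of 17 higher, and cell cycle genes at -0.15 with 0 of 32. Voltage-gated channels were at 0.62 with a floor at percentile 75, and skeletal muscle at 0.077 with no floor.

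Of the remaining neuronal lists in sorted cells against the array labelled endogenous PV, all within the percentile limits, the REST-related list was at 0.25 with 3 of 14 higher, glutamatergic neurons at 0.23 with 2 of 6 and synaptic vesicle and active zone at 0.20 with 3 of 18. Medial ganglionic eminence regulators were at 0.033 with 0 of 8 differing 2-fold, GABA and glutamate receptors at -0.056 with 0 of 10 and other transmitter systems at -0.058 with 0 of 4. Glutamatergic neurons turned to -0.062 with no floor and were at 0.046 with the mean of probe sets. The higher floor turned medial ganglionic eminence regulators to -0.14, which were also negative with no floor, and gave 0.40 for synaptic genes and 0.039 for the REST-related list.

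In the same pair Reg3g was at least 49.1-fold lower and Lilrb4a 28.7-fold lower in sorted cells, and Apod was at least 27.9-fold lower. Acpp was 7.26-fold and Kcnn3 6.95-fold higher. GABAergic neuron genes had a median of 0.26 with 0 of 6 differing 2-fold, and parvalbumin interneuron genes a median of 0.17 with 2 of 14 higher, with Hapln4 higher by 1.32 and Pvalb by 0.82. A percentile 75 floor gave 0.63 for GABAergic neurons, 0.026 for parvalbumin interneurons and 0.35 for pan-neuronal genes. Without a floor GABAergic neurons were at 0.031 and proneural regulators at 0.11. Overall counts were 302 genes higher and 253 lower, with a technical spread of 0.32 and 62 genes from simulated unchanged arrays. The share of higher genes was 54.4%, but 49.0% after quantile normalization, 49.1% with no floor and 46.5% with a floor at percentile 75. At 4-fold, 17 genes were higher and 65 lower.

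The array labelled endogenous PV had higher interferon-response genes and lower cell cycle genes than MEF. Interferon-response genes had a median log2 difference of 1.36, with 20 of 25 at least 2-fold higher and 0 lower. Cxcl10 was higher by 3.07, Ccl5 by 3.01 and Irf7 by 2.97. Cell cycle genes had a median of -0.84 with 12 of 34 lower and 0 higher, Cenpe at -1.62. Hox genes had a median of 0.57 with 2 of 24 higher, among them Hoxc8 by 1.26, and glycolysis genes a median of 0.38 with 3 of 14 higher, among them Pfkl by 1.62. Fibroblast and matrix genes had a median of -0.011, with 4 of 36 higher and 5 lower, Fap at 1.57 and S100a4 at -2.35. That median was -0.30 after housekeeping centring and turned positive with a floor at percentile 75. The macrophage median was 0.20 with 3 of 16 higher and 0 lower, negative after housekeeping centring. Pan-neuronal genes had a median of 0.07 over 20 members with 0 at least 2-fold different, GABAergic neuron genes 0.06 with 1 of 6 higher, and parvalbumin interneuron genes 0.04 over 14 members with 0 at least 2-fold different. These 3 medians were negative after housekeeping centring, which gave 0.29 for Hox genes and 0.091 for glycolysis. At the higher floor parvalbumin interneurons turned to -0.54, GABAergic neurons were at 0.35, Hox genes at 0.083 and cell cycle genes at -0.47, and without a floor parvalbumin interneurons were at 0.19.

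Folh1 was at least 32.0-fold higher on the array labelled endogenous PV than in MEF. Hp, which encodes the acute-phase protein haptoglobin, was 20.5-fold higher, Gdf10 19.8-fold and Reg3g 14.9-fold. Mmp13 was 13.6-fold lower. Neuronal lists above the upper percentile limit on that array were GABA and glutamate receptors at 0.35 with 1 of 9 higher, synaptic vesicle and active zone at 0.34 with 3 of 17 higher and proneural regulators at 0.31 with 0 of 19 differing 2-fold. Receptors were at 0.79 with a floor at percentile 75, synaptic genes at 0.056 after housekeeping centring, and proneural regulators at 0.027 after that centring and 0.17 with no floor. Neuronal lists within the limits included voltage-gated channels at 0.11 with 1 of 9 higher, the REST-related list at 0.10 with 0 of 14, other interneuron classes at 0.094 with 3 of 9 higher and 1 lower, and glutamatergic neurons at -0.058 with 0 of 7. Housekeeping centring gave -0.19, -0.17, -0.21 and -0.34 in the same order. With a floor at percentile 75 other interneuron classes were at 2.09 and voltage-gated channels at 0.45, and glutamatergic neurons turned positive, as they did with no floor, where other interneuron classes turned negative. The p53 response was at 0.35 with 1 of 16 higher, and 0.062 after housekeeping centring, and cerebellum and hindbrain at 0.29 with 1 of 6 higher. Smooth muscle and myofibroblast genes were at -0.30 with 1 of 17 higher, cholesterol synthesis at -0.26 with 0 of 18 differing 2-fold and skeletal muscle at -0.22 with 2 of 14 higher. The first 2 were at -0.58 and -0.54 after housekeeping centring, and skeletal muscle turned to 1.37 with a floor at percentile 75. In all 473 genes were at least 2-fold higher and 215 lower, with a technical spread of 0.42 and 328 genes from simulated unchanged arrays. The share of higher genes was 68.8%, against 31.3% after housekeeping centring and 89.2% at 4-fold.

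**Figure D3:**
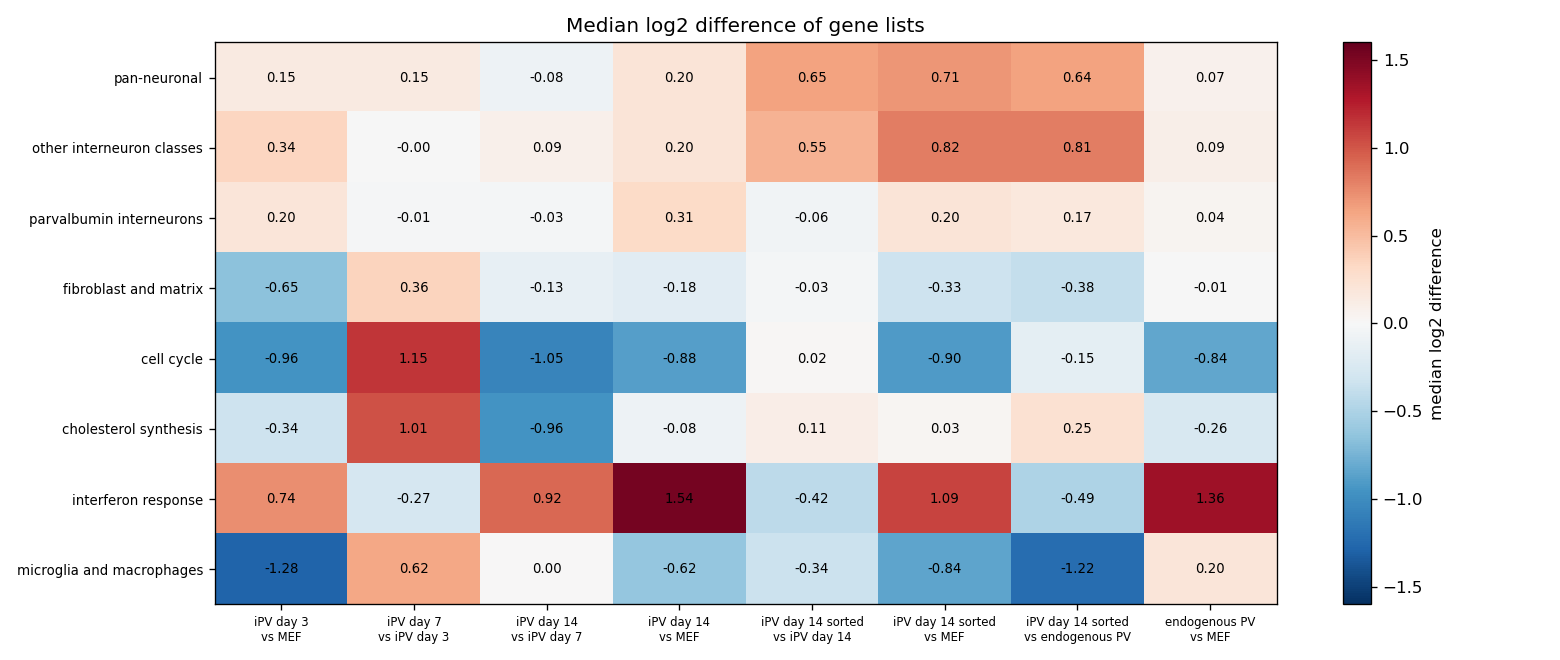
Colours and printed values give the median log2 difference of 8 gene lists in each of the 8 comparisons, with the array named first minus the one named second. Pan-neuronal genes were highest where sorted cells were compared, at 0.65, 0.71 and 0.64, and were at 0.07 on the array labelled endogenous PV against MEF, a value that was negative after housekeeping centring.

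Across all genes, every induced array was closer to the array labelled endogenous PV than to MEF. Pearson correlations, computed across genes that are not independent replicates, were 0.963 at day 3, 0.978 at day 7, 0.974 at day 14 and 0.968 in sorted cells with the array labelled endogenous PV, and 0.957, 0.962, 0.956 and 0.940 with MEF. The excess over MEF was smaller with no floor, at 0.003 for day 3, 0.0079 for day 7, 0.0118 for day 14 and 0.0164 for sorted cells. With a floor at percentile 75 it was 0.0027 for day 3 and 0.028 for day 7. The array labelled endogenous PV and MEF correlated at 0.959. Of 102 genes at least 4-fold different between those 2 arrays, 91 were higher and 11 lower on the former. At least 2-fold in the same direction from MEF were 62.7% of them at day 3, 80.4% at day 7, 76.5% at day 14 and 77.5% in sorted cells. Unchanged arrays sharing the MEF values gave 0%, 2.46%, 4.32% and 10.1% in simulation. The simulation held only technical spread. It cannot show what a peculiarity of the single MEF culture would give, since that array enters both differences. Differences with no array in common correlated weakly with the difference between the array labelled endogenous PV and MEF. The correlation was 0.141 for sorted minus unsorted cells, 0.0508 for day 14 minus day 7, which turned to -0.0546 with a floor at percentile 75, and 0.149 for day 7 minus day 3, which was 0.0957 with no floor and 0.268 with that floor. Without a floor the day 14 minus day 7 value was 0.0819, and after quantile normalization it was 0.0284. Since the array labelled endogenous PV had the fibroblast and marker values given above, these similarities are to that array as measured.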

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

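All tests of explanations in this part were chosen after the results were seen. Probe sets without a gene name here were outside the comparisons, and some were at least 4-fold above MEF: 23 at day 3, 31 at day 7, 29 at day 14, 28 in sorted cells and 41 on the array labelled endogenous PV. For 7 lists the median against MEF had opposite signs in sorted cells and on the array labelled endogenous PV, and this difference was not tested. In 4 of them both medians lay within their technical error and were negative on both arrays after housekeeping centring. These were GABAergic neurons at -0.049 and 0.063, medial ganglionic eminence regulators at 0.0017 and -0.0090, other transmitter systems at -0.072 and 0.088, and astrocytes at 0.18 and -0.014. That centring moved the median of all genes to -0.31 and -0.28 on these arrays against MEF. Small medians turn negative by that shift alone, so the shared sign says nothing about the lists. For the other 3, where sorted cells against that array lay beyond the percentile limits, the medians were 0.029 and -0.22 for skeletal muscle, 0.031 and -0.26 for cholesterol synthesis, and -0.84 and 0.20 for macrophage genes. The sorted values of skeletal muscle and cholesterol synthesis lay within their error. They took the sign of the other array after housekeeping centring, at -0.14 and -0.28, which a shift of all genes gives to medians so near 0. Cholesterol synthesis in sorted cells was also negative after quantile normalization. Skeletal muscle took the same sign on both with no floor, at -0.14 in sorted cells, and with a floor at percentile 75, at 1.45 and 1.37. Macrophage genes on the array labelled endogenous PV turned to -0.079 after housekeeping centring.

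On the array labelled endogenous PV, 4 of 36 fibroblast and matrix genes were at least 2-fold above MEF and 5 below. RNA mainly from parvalbumin neurons would put the list far below MEF, but its median difference was -0.011. The 2 rescalings tried did not put it far below MEF either, since the lowest median over quantile normalization and housekeeping centring was -0.30. Housekeeping centring only shifts all genes of a pair by 1 constant, so other faults of scaling were not tested. RNA from a fibroblast or induced culture, by a wrong label or a mixture, stays open, and the labels carry the fibroblast culture text for this sample too. Its correlations with the induced arrays were 0.9626 with day 3, 0.9779 with day 7, 0.9744 with day 14 and 0.9678 with sorted cells. Correlations between 2 induced arrays ran from 0.9684, for day 7 with sorted cells, to 0.9771, for day 7 with day 14. The value with day 7 lay above this range, so this array was as close to day 7 as any induced array was. The values with day 3 and sorted cells lay below the range. RNA from an induced culture could give the day 7 value, but with 1 array per group these correlations do not decide it.

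Cell cycle and cholesterol genes were high at day 7 against day 3. The tables argue against scaling between arrays as the whole cause, since the lowest median of both lists after rescaling was 0.84. The state of the culture on the day of harvest, such as density or fresh medium, cannot be told apart from the day of induction, because there was 1 array per day. A change with the day of induction also stays open and was not tested.

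Macrophage genes were low at day 3 against MEF and in sorted cells against the array labelled endogenous PV. Quantile normalization and housekeeping centring did not bring the medians near 0, and the highest median after them was -1.24. Housekeeping centring only shifts all genes of a pair by 1 constant, so other faults of scaling were not tested. Fewer macrophages among the cells and lower values within the cells cannot be told apart, since both would put most members below 0, as 93.3% or more were in both comparisons, 14 of 15 and 15 of 16. Lyz2 had 9.78 in MEF, 6.76 at day 3, 6.03 in sorted cells and 10.05 on the array labelled endogenous PV, while Tmem119 had 6.29, 7.64, 8.03 and 8.11 on the same arrays, and 0 genes of the list were in another list. What the sort for green fluorescence removed was not measured. Without a sort the list was at -1.28 at day 3 and -0.62 at day 14 against MEF, and sorted against unsorted cells were at -0.34.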

How the results depend on the processing

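The added alternative of 5 arrays, and the tolerances, were chosen after the results were seen. With 1 array per group, no spread between cultures limits these values, and genes near the floor have little signal over background. All 16 counts stayed within 1.5 times under quantile normalization and the mean of probe sets. The 5 other arrays were used for the 6 comparisons without the array labelled endogenous PV, where 12 of 12 counts stayed within 1.5 times, and 0 of 107 list medians and 0 of 117 single genes moved. Single genes moved by more than 1 technical spread in 81 of 150 values with a floor at percentile 75, 19 with housekeeping centring, 15 with no floor, 7 with the mean of probe sets and 0 with quantile normalization. The values below are those that moved further than their tolerance, and the cause was not tested except that a 4-fold threshold or a higher floor counts fewer genes by construction.

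Centring on housekeeping genes changed counts of genes. For day 14 against MEF the array medians it used were 8.94 and 8.45, further apart than the median difference of housekeeping genes, 0.25. Centring moved the median of all genes to -0.46 there. It gave 194 higher and 752 lower for day 3 against MEF, 181 higher and 250 lower for day 7 against day 3, 180 higher and 1103 lower for day 14 against MEF and 464 higher and 73 lower for sorted against unsorted cells. The other counts were 439 higher and 782 lower for sorted cells against MEF and 254 higher and 557 lower for the array labelled endogenous PV against MEF. It moved 93 list medians and turned the sign of 7 more that were beyond the percentile limits. For day 3 against MEF this was respiratory chain. For day 14 against MEF these were parvalbumin interneurons, synaptic vesicle and active zone, GABA and glutamate receptors, smooth muscle and myofibroblast, respiratory chain and Hox genes. Day 3 against MEF had -0.16 for GABAergic neurons, -0.012 for parvalbumin interneurons, -0.13 for pan-neuronal, -0.93 for fibroblast and matrix and 0.092 for other interneuron classes. Glutamatergic neurons had -0.57, with 0.0044 for GABA and glutamate receptors, 0.084 for proneural and neurogenic regulators, -1.24 for cell cycle and 0.53 for interferon response, in day 3 against MEF. P53 response and apoptosis had 0.0016, with -0.62 for cholesterol synthesis, -0.037 for respiratory chain, -1.49 for microglia and macrophages and 0.093 for cerebellum and hindbrain, in day 3 against MEF. Hox genes had 0.21, in day 3 against MEF. Day 7 against day 3 had -0.19 for parvalbumin interneurons, -0.028 for pan-neuronal, 0.18 for fibroblast and matrix, 0.086 for synaptic vesicle and active zone and 0.97 for cell cycle. Interferon response had -0.44, with 0.84 for cholesterol synthesis, 0.20 for glycolysis, 0.25 for astrocytes and 0.46 for microglia and macrophages, in day 7 against day 3. Day 14 against day 7 had 0.25 for cAMP and activity response. Day 14 against MEF had -0.12 for GABAergic neurons, -0.18 for parvalbumin interneurons, -0.19 for pan-neuronal, -0.68 for fibroblast and matrix and -0.062 for synaptic vesicle and active zone. GABA and glutamate receptors had -0.0078, with -0.11 for smooth muscle and myofibroblast, -1.37 for cell cycle, 0.060 for cAMP and activity response and 1.05 for interferon response, in day 14 against MEF. P53 response and apoptosis had 0.19, with 0.24 for glycolysis, -0.055 for respiratory chain, -1.07 for microglia and macrophages and -0.17 for Hox genes, in day 14 against MEF. Sorted against unsorted cells had 0.13 for parvalbumin interneurons, 0.83 for pan-neuronal, 0.16 for fibroblast and matrix, 0.74 for other interneuron classes and 0.16 for glutamatergic neurons. Synaptic vesicle and active zone had 0.34, with 0.11 for GABA and glutamate receptors, 0.40 for proneural and neurogenic regulators, -0.31 for smooth muscle and myofibroblast and -0.23 for interferon response, in sorted against unsorted cells. Glycolysis had -0.10, with -0.15 for microglia and macrophages, 0.63 for Hox genes and 0.66 for REST target repressors and neuronal splicing, in sorted against unsorted cells. Sorted cells against MEF had -0.10 for parvalbumin interneurons, 0.29 for pan-neuronal, -0.64 for fibroblast and matrix, -0.26 for medial ganglionic eminence regulators and 0.55 for other interneuron classes. Glutamatergic neurons had -0.31, with 0.24 for synaptic vesicle and active zone, 0.064 for voltage-gated channels, 0.16 for proneural and neurogenic regulators and -0.54 for smooth muscle and myofibroblast, in sorted cells against MEF. Skeletal muscle had -0.14, with -1.21 for cell cycle, -0.090 for cAMP and activity response, 0.78 for interferon response and 0.21 for p53 response and apoptosis, in sorted cells against MEF. Cholesterol synthesis had -0.28, with 0.15 for glycolysis, 0.0006 for respiratory chain, -0.13 for astrocytes and -0.42 for Schwann cell and neural crest, in sorted cells against MEF. Hox genes had 0.58, with 0.19 for REST target repressors and neuronal splicing and -0.17 for housekeeping, in sorted cells against MEF. The array labelled endogenous PV against MEF had -0.20 for GABAergic neurons, -0.13 for parvalbumin interneurons, -0.19 for pan-neuronal, -0.30 for fibroblast and matrix and -0.27 for medial ganglionic eminence regulators. Other interneuron classes had -0.21, with -0.34 for glutamatergic neurons, -0.22 for other transmitter systems, 0.056 for synaptic vesicle and active zone and -0.19 for voltage-gated channels, in the array labelled endogenous PV against MEF. Proneural and neurogenic regulators had 0.027, with -0.58 for smooth muscle and myofibroblast, -1.12 for cell cycle, 1.08 for interferon response and 0.062 for p53 response and apoptosis, in the array labelled endogenous PV against MEF. Cholesterol synthesis had -0.54, with 0.091 for glycolysis, -0.25 for astrocytes, -0.079 for microglia and macrophages and 0.29 for Hox genes, in the array labelled endogenous PV against MEF. REST target repressors and neuronal splicing had -0.17, in the array labelled endogenous PV against MEF.

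A floor at percentile 75 lowered counts. It gave 165 higher and 183 lower for day 3 against MEF, 157 higher and 61 lower for day 7 against day 3, 61 higher and 88 lower for day 14 against day 7 and 271 higher and 140 lower for day 14 against MEF. The other counts were 135 higher and 75 lower for sorted against unsorted cells, 438 higher and 202 lower for sorted cells against MEF, 139 higher and 160 lower for sorted cells against the array labelled endogenous PV and 274 higher and 100 lower for the array labelled endogenous PV against MEF. It turned the sign of skeletal muscle for the array labelled endogenous PV against MEF, which was beyond the percentile limits. Only members above this floor on at least 1 array counted, so a median can rest on few members. This floor left 6 of the list medians without a measured member. Of the list medians, 80 moved. Day 3 against MEF had 0.32 for GABAergic neurons, -0.14 for parvalbumin interneurons, -0.11 for pan-neuronal, 1.5 for other interneuron classes and -0.58 for glutamatergic neurons. Proneural and neurogenic regulators had 0.58, with -0.50 for cell cycle, 0.49 for interferon response, 0.16 for respiratory chain and -0.017 for astrocytes, in day 3 against MEF. Microglia and macrophages had -1.09, with 0.14 for cerebellum and hindbrain and 0.35 for Hox genes, in day 3 against MEF. Day 7 against day 3 had -0.32 for parvalbumin interneurons, 0.44 for pan-neuronal, 0.78 for cell cycle, 0.77 for cholesterol synthesis and 0.090 for astrocytes. Microglia and macrophages had 1.22, in day 7 against day 3. Day 14 against day 7 had 0.83 for parvalbumin interneurons, -0.48 for pan-neuronal, -0.71 for cell cycle, 0.95 for cAMP and activity response and 0.79 for interferon response. Cholesterol synthesis had -0.80, with -0.090 for astrocytes and 0.52 for endothelium, in day 14 against day 7. Day 14 against MEF had -0.23 for pan-neuronal, 0.14 for GABA and glutamate receptors, -0.44 for cell cycle, 0.80 for cAMP and activity response and 1.09 for interferon response. Microglia and macrophages had -0.89, in day 14 against MEF. Sorted against unsorted cells had 0.55 for GABAergic neurons, 0.39 for pan-neuronal, 0.042 for medial ganglionic eminence regulators, 0.43 for other interneuron classes and 0.22 for glutamatergic neurons. Synaptic vesicle and active zone had 0.66, with 0.54 for voltage-gated channels, 0.36 for proneural and neurogenic regulators, 0.34 for Hox genes and 0.13 for REST target repressors and neuronal splicing, in sorted against unsorted cells. Sorted cells against MEF had 0.98 for GABAergic neurons, 0.026 for parvalbumin interneurons, 0.31 for pan-neuronal, 0.23 for glutamatergic neurons and 0.92 for synaptic vesicle and active zone. Voltage-gated channels had 1.07, with 0.88 for GABA and glutamate receptors, 0.81 for proneural and neurogenic regulators, 1.45 for skeletal muscle and -0.47 for cell cycle, in sorted cells against MEF. Interferon response had 0.80, with 0.93 for oligodendrocyte lineage, -0.49 for microglia and macrophages, -0.65 for endothelium and 0.32 for Schwann cell and neural crest, in sorted cells against MEF. Cerebellum and hindbrain had 0.50, with 0.69 for Hox genes and 0.12 for REST target repressors and neuronal splicing, in sorted cells against MEF. Sorted cells against the array labelled endogenous PV had 0.63 for GABAergic neurons, 0.026 for parvalbumin interneurons, 0.35 for pan-neuronal, -0.14 for medial ganglionic eminence regulators and 1.17 for other interneuron classes. Synaptic vesicle and active zone had 0.40, with 0.62 for voltage-gated channels, 0.40 for skeletal muscle, -0.84 for microglia and macrophages and 0.039 for REST target repressors and neuronal splicing, in sorted cells against the array labelled endogenous PV. The array labelled endogenous PV against MEF had 0.35 for GABAergic neurons, -0.54 for parvalbumin interneurons, 2.09 for other interneuron classes, 0.45 for voltage-gated channels and 0.79 for GABA and glutamate receptors. Skeletal muscle had 1.37, with -0.47 for cell cycle, 1.18 for interferon response, 0.31 for astrocytes and 0.083 for Hox genes, in the array labelled endogenous PV against MEF. The correlation with the array labelled endogenous PV minus that with MEF was 0.0027 for iPV day 3 and 0.028 for iPV day 7. The correlation with the difference between the array labelled endogenous PV and MEF was -0.0546 for day 14 against day 7 and 0.268 for day 7 against day 3.

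Leaving out the floor raised counts. It gave 557 higher and 548 lower for day 3 against MEF, 313 lower for day 7 against day 3, 264 higher and 296 lower for day 14 against day 7 and 503 lower for day 14 against MEF. The other counts were 425 higher and 326 lower for sorted against unsorted cells, 612 lower for sorted cells against MEF, 446 lower for sorted cells against the array labelled endogenous PV and 397 lower for the array labelled endogenous PV against MEF. It moved 24 list medians and turned the sign of 4 more that were beyond the percentile limits. For day 3 against MEF these were glutamatergic neurons and astrocytes. For day 14 against day 7 this was endothelium. For sorted against unsorted cells this was proneural and neurogenic regulators. Day 3 against MEF had 0.031 for glutamatergic neurons, 0.23 for proneural and neurogenic regulators, 0.10 for astrocytes, -0.97 for microglia and macrophages and 0.14 for cerebellum and hindbrain. Day 7 against day 3 had 0.23 for astrocytes. Day 14 against day 7 had -0.063 for endothelium. Day 14 against MEF had 0.14 for GABA and glutamate receptors and 1.43 for interferon response. Sorted against unsorted cells had -0.16 for GABAergic neurons, -0.28 for glutamatergic neurons, 0.16 for voltage-gated channels and -0.036 for proneural and neurogenic regulators. Sorted cells against MEF had 0.27 for other interneuron classes, 0.46 for GABA and glutamate receptors, 0.15 for proneural and neurogenic regulators, -0.14 for skeletal muscle and -0.10 for cerebellum and hindbrain. Sorted cells against the array labelled endogenous PV had 0.031 for GABAergic neurons, 0.55 for other interneuron classes, -0.062 for glutamatergic neurons, 0.11 for proneural and neurogenic regulators and 0.077 for skeletal muscle. Interferon response had -0.59, with -1.32 for microglia and macrophages, in sorted cells against the array labelled endogenous PV. The array labelled endogenous PV against MEF had 0.19 for parvalbumin interneurons, 0.17 for proneural and neurogenic regulators and 0.17 for astrocytes. The correlation with the array labelled endogenous PV minus that with MEF was 0.003 for iPV day 3, 0.0079 for iPV day 7, 0.0118 for iPV day 14 and 0.0164 for iPV day 14 sorted. The correlation with the difference between the array labelled endogenous PV and MEF was 0.0819 for day 14 against day 7 and 0.0957 for day 7 against day 3.

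A threshold of 4-fold lowered counts. It gave 62 higher and 48 lower for day 3 against MEF, 23 higher and 2 lower for day 7 against day 3, 6 higher and 15 lower for day 14 against day 7 and 72 higher and 31 lower for day 14 against MEF. The other counts were 9 higher and 13 lower for sorted against unsorted cells, 140 higher and 50 lower for sorted cells against MEF, 17 higher and 65 lower for sorted cells against the array labelled endogenous PV and 91 higher and 11 lower for the array labelled endogenous PV against MEF. Quantile normalization moved 8 list medians. Day 14 against day 7 had -0.0056 for pan-neuronal. Day 14 against MEF had 0.45 for Hox genes. Sorted against unsorted cells had 0.50 for pan-neuronal, 0.061 for synaptic vesicle and active zone, 0.15 for proneural and neurogenic regulators and 0.31 for Hox genes. Sorted cells against MEF had 0.23 for skeletal muscle and -1.06 for cell cycle. The correlation with the difference between the array labelled endogenous PV and MEF was 0.0284 for day 14 against day 7. The mean of probe sets moved 4 list medians. Day 14 against MEF had 0.14 for smooth muscle and myofibroblast. Sorted against unsorted cells had -0.16 for glycolysis. Sorted cells against MEF had 0.45 for pan-neuronal. Sorted cells against the array labelled endogenous PV had 0.046 for glutamatergic neurons.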

Other observations

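All genes in this part were chosen after their values were seen, and no list of them was tested. Ddit3, a stress-response transcription factor, had 8.91 at day 3, against 7.11 in MEF, 6.83 at day 7 and 7.73 at day 14. Hspa5, a chaperone of the endoplasmic reticulum, had 9.84 at day 3, 8.67 in MEF, 8.39 at day 7 and 8.98 at day 14. Herpud1, a factor of protein degradation there, had 9.20 at day 3, 8.0 in MEF, 7.74 at day 7 and 8.08 at day 14. Atf4, a transcription factor, had 8.91 at day 3 and 8.75 at day 14, which differed by less than the technical spread, and 8.11 in MEF.

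Saa3, a serum amyloid protein, had 10.12 in MEF, 12.54 at day 3, 13.13 at day 7, 12.69 at day 14, 12.45 in sorted cells and 13.37 on the array labelled endogenous PV. Lcn2, an iron-binding lipocalin, had 8.98, 10.99, 11.77, 11.71, 11.31 and 12.18 on the same arrays. The prolactin family gene Prl8a9 had 5.37, 8.05, 7.34, 9.58, 7.61 and 5.75 in that order. Xist, expressed from the inactive X chromosome, had 9.77 in sorted cells and lay between 8.12 and 8.95 on the other arrays. The Y-linked gene Eif2s3y lay between 7.01 on the array labelled endogenous PV and 7.87 at day 3. Uty, also Y-linked, lay between 6.40 in sorted cells and 7.46 at day 3. All were above the floor on every array.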
